A study of Streptomyces tsukubensis NRRL18488 with 54 samples.

How the data were processed

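Total RNA from flask cultures of Streptomyces tsukubensis was measured on 54 microarrays that cover 3 carbon sources and 10 times from 70 to 148 h. Per the labels' protocols, RNA was reverse transcribed with random hexamers into Cy3-labelled cDNA and hybridized together with Cy5-labelled genomic DNA, the same reference sample on every array and with no exchange of dyes. The scanner files hold spot and local background intensity values in both channels, extracted with Agilent Feature Extraction and not normalized, per the file headers. The processed-signal intensity columns of the same files were corrected for background by that program, per the file headers. The deposited series table holds log2 values that the authors made with limma 3.20, per the submitters' processing notes, for 8475 of 15744 spots. The direction of these log2 values, Cy3 over Cy5, was found by matching the deposited table to the scanner values (r = 0.932 to 0.972 with the values used here), their columns had medians of −0.250 to 0.0523, and the background correction and normalization behind them are not given in the sources used here. As that table held 2 of the 32 fkb features, the report used the scanner intensities and kept the table as an alternative.

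Mean spot signals were corrected for the local background with normexp (offset 50) in limma 3.58.1 under R 4.3.3, log2(Cy3/Cy5) was computed, each array was centred on the median of its non-tile features, and replicate spots of a feature were averaged. On the glucose array of replicate 2 at 70 h, 5 spots with a huge local background (up to 38398) spoiled the normexp fit. Local backgrounds that Feature Extraction marked as outliers were therefore replaced by the array's median background, on all arrays, a change made after the data were seen, and the unrepaired version was kept as an alternative. After 536 control spots were set aside, the array held 9534 features and 4255 tile probes in 16 labelled regions. The filter on dim features removed 0 of the 9534, 8237 lay above background on all arrays, and 18 had no value in some group, so 9531 to 9534 features entered each test. Signal over background and the number of arrays limit precision: 89.2% to 99.9% of spots per array lay well above background in Cy3.

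Feature identifiers carried no gene names, and 0 of the 9534 matched the reference table of locus tags. Features were tied to the labelled tiled regions by shared 20-letter sequences (at least 10 shared), which tied 70 features. Of these 51 were named: 32 in the fkb region, 4 in the pho region, and the rest in 13 regions of 1 feature each and in rshA. Strand was read from the tile probes relative to the nearest tied feature. No gene could be named within the fkb region, so its features are numbered by position.

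A cell-means model with a coefficient for each of 30 groups was fitted with limma (24 residual and 4.08 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 12 contrasts were each source at 70.7 h and late (mean of 89, 92 and 100 h) against its own 70 h, and the differences of these responses between sources. An F test compared the 3 series at 70 h. The comparisons, the late window, the tests, the gene lists and the first set of alternatives were chosen before the data were examined. Of 18 lists fixed then, the tacrolimus cluster and glycolysis had members enough to test, 3 had 1 named member each (glnR for nitrogen, dasR for sugar uptake, wblA for aerial growth), and 12 had none. The remaining list, that of phosphate genes, was tested on the pho region, a choice made after its label was seen. Lists were tested with limma's camera, with its preset correlation between genes of 0.01, adjusted over 36 tests, and again with an estimated correlation.

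The rule for named genes was, per contrast, the 5 largest rises and the 5 largest falls past the threshold with a known product and the same sign in both cultures, every tacrolimus gene, and up to 4 members of each list. As no identifier could be paired with a product, only features of the labelled regions could be named. The regions atrA, afsRS, rshA, SCO6008, mmyB and pho, the identifiers printed and the single fkb features singled out were named after their values were seen. The comparisons of single times, such as 100 h against 92 h, were also chosen then.

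Replicate numbers pair the samples, because per the labels the same culture was sampled at each time. The differences between the 2 cultures of a source correlated between times in 28 of 28 pairs of times in glucose (r = 0.231 to 0.856, median 0.611), 28 of 28 in glycerol (0.182 to 0.794, median 0.459) and 27 of 28 in maltose (−0.0569 to 0.779, median 0.381), over features that are not independent replicates. The fit with culture as a fixed block is given beside each count it moved by over 1.5 times. It was also read for every named feature and list, after the results were seen. Arrays lay on 7 slides in 2 scan sets. Up to 100 h each scan set held 1 culture of each source, so that culture and scan set cannot be told apart within a source, and values per scan set are values per culture. Comparisons of one source with another use the same scan sets on both sides.

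The fit was tested on simulated data with 9534 features of which 200 were changed. It recovered 78.8% of 4-fold, 17.9% of 2-fold and 2.99% of 1.5-fold changes for glucose at 70.7 h, 89.4%, 25.4% and 2.99% for glucose late, and 66.7%, 11.9% and 1.49% for glucose against maltose late. With no feature changed it made 0 calls over the 12 contrasts. The simulated arrays were independent, with no culture or slide effect and the same spread in every series, so these rates may not hold for the data. Alternatives covered background correction, normalization, filters, the processed signals, the authors' table, the Cy3 channel alone, blocks for culture or slide, a pooled baseline, fits on single series and the removal of each culture. The 124 and 148 h samples, with 1 culture per source, entered the fit but no comparison. Tables were handled with Python 3.11.15 and numpy 2.4.6, figures drawn with matplotlib 3.10.9, and statmod 1.5.0 was used for slide as a random block.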

Results

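The series followed the transcriptome of Streptomyces tsukubensis after feeding with glucose, glycerol or maltose. This soil bacterium makes the immunosuppressant tacrolimus (FK506), and the study concerned carbon sources that repress tacrolimus formation. Flask cultures were sampled at 70 h, before any feeding, and then received a carbon source. The series description gives the added amounts as 0.22 M or 2% w/v glucose, 0.22 M or 4% glycerol and 0.11 M or 3% maltose, and these percentages do not match the molarities, so that the doses are uncertain. Sampling went on at 70.7, 72, 76, 80, 89, 92 and 100 h in 2 cultures per source and at 124 and 148 h in 1 culture per source. This gave 54 arrays in 30 groups, drawn from 6 cultures that were each sampled repeatedly. Each array set Cy3-labelled cDNA against a common Cy5-labelled genomic DNA reference, so a level is the log2 ratio of cDNA to genomic DNA for 1 feature, centred on the array median.

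Levels were measured for 9534 features, of which 51 carried a name through the 16 labelled tiled regions of the array design. The median Cy3 intensity per array ran from 159 (glucose replicate 1 at 89 h) to 1465 (maltose replicate 1 at 70 h), and 89.2% to 99.9% of spots lay well above background in Cy3. Across features, which are not independent replicates, the 2 cultures of a group correlated at r = 0.846 (maltose at 70 h) to r = 0.968 (glucose at 72 h). The number of arrays limits the precision of every value, and errors on log2 differences are limma standard errors that pool the spread between the cultures of 24 groups. The main fit counts repeated samples of a culture as independent, although late values rest on 2 cultures per source. Its errors and p-values therefore do not measure how far a late response varies between cultures. Late values are means of 89, 92 and 100 h set against 70 h of the same series. No culture without an added carbon source was followed after 70 h, so changes from 70 h mix feeding with time in culture. Of the 46 named-gene differences called in the 12 comparisons outside the fkb region, within-array loess normalization left 12 past the threshold and turned 1. Fits on only the series compared ended 11 of these calls, leaving out the bright maltose array at 70 h 10, keeping marked backgrounds 8, slide as a fixed term 7 and a pooled baseline 4. Leaving out glucose replicate 1 or 2 ended 27 or 28 of these calls, leaving out either glycerol replicate ended 17, and 3 passed in every setting. With culture as a block all 46 were kept and 20 were gained. Of 39 late calls, late as 100 h alone ended 11, and late without 100 h ended 9. Loess follows the mean intensity of both channels, which with a common genomic DNA reference moves mainly with Cy3. It can therefore remove real changes, and a call lost under loess alone was not shown to be false.

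Before feeding, the 3 series differed at 1 feature, stsu_s_0336, which was named for being the lone call. Its level was −0.94 in the glucose series, 1.48 in the glycerol series and 1.65 in the maltose series (limma F test, adjusted p = 0.00277). An unadjusted p under 0.05 was met by 1323 of 9531 features, where 476.55 would be met by chance. The call count was 2403 without maltose replicate 2 and 0 without glucose replicate 1.

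The fkb region stayed low after glucose and glycerol and was high in maltose cultures at 100 h. It is labelled for the cluster that encodes the polyketide synthase and the accessory enzymes of tacrolimus synthesis. Which of its features are tacrolimus genes was not identified, and all are called the cluster here. Its 32 features averaged −0.65 ± 0.29, −0.73 ± 0.45 and −0.76 ± 0.07 at 70 h in the glucose, glycerol and maltose series (SD, n = 2 cultures). The maltose mean was −1.02 ± 0.08 at 92 h and 3.67 ± 0.44 at 100 h (SD, n = 2 cultures), a rise of 4.44 over 70 h, or 21.7-fold. In that comparison 29 of the 32 features rose and 0 fell, and the mean change was 4.18 in the first scan set and 4.70 in the second. From 92 to 100 h the cluster rose 25.8-fold (4.69 on the log2 scale, 29 of 32 features), while the differences in the glucose and glycerol series were 0.07 and 0.06, with 0 of 32 features called by limma. In the glucose and glycerol series the cluster mean stayed between −1.15 and −0.88 at every time from 70.7 to 148 h. In the maltose culture that was followed further it was 2.29 at 124 h and 1.05 at 148 h.

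**Figure D1:**
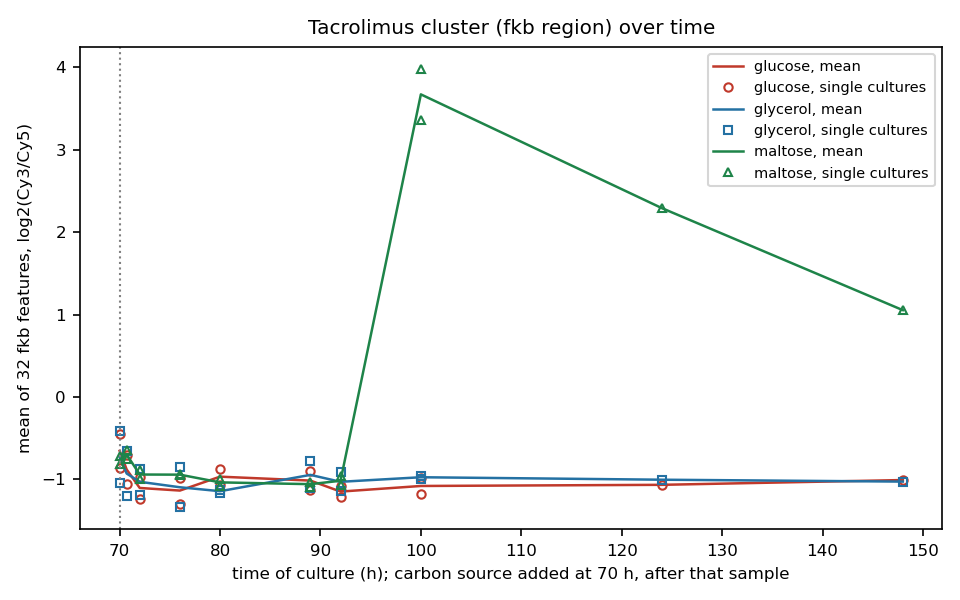
Mean log2(Cy3/Cy5) of the 32 fkb features (y axis) against culture time in hours (x axis), with open symbols for single cultures, lines for the mean of each carbon source and a dotted line at the addition at 70 h. The maltose cultures reached 3.98 and 3.36 at 100 h, when glucose and glycerol cultures lay between −1.18 and −0.96.

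At 100 h the response of the cluster was 29.1-fold lower with glucose than with maltose (−4.86 on the log2 scale, 27 of 32 features lower) and 25.6-fold lower with glycerol than with maltose (−4.68, 27 of 32 lower). By scan set these differences were −4.71 and −5.02 for glucose and −4.72 and −4.64 for glycerol. Both calls by limma's camera held with an estimated correlation between genes (adjusted p = 0.000524 and 0.00142). The single-time comparison at 100 h was chosen after the data were seen. In the late comparison fixed beforehand, the fkb mean was −1.72 for glucose against maltose (24 of 32 features lower, 26 lower and 1 higher when adjusted over the list alone) and −1.55 for glycerol against maltose (25 lower, and 25 lower and 1 higher over the list alone). By scan set the late differences were −1.76 and −1.69 for glucose, and −1.68 and −1.41 for glycerol. Camera with its preset correlation gave adjusted p = 1.76e-15 and 3.04e-10, and with an estimated correlation adjusted p = 0.123 and 0.202, so the late calls were lost. The late differences rested on the 100 h samples: over 89 and 92 h alone they were −0.15 and 0.02.

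Single fkb features differed in how far they moved in maltose at 100 h. The largest changes were 117-fold for fkb 10 (6.87 ± 0.38), 116-fold for fkb 30 (6.85 ± 0.35), 108-fold for fkb 29 (6.75 ± 0.39, dim on every array of 1 group), 102-fold for fkb 12 (6.67 ± 0.61) and 91.4-fold for fkb 11 (6.51 ± 0.37), numbered by position along the tiled region. Smaller rises were seen at fkb 24 (2.88-fold, 1.52 ± 0.28), fkb 32 (2.26-fold, 1.18 ± 0.37) and fkb 27 (1.73-fold, 0.79 ± 0.27). The 3 features that did not pass were fkb 1 (−0.42 ± 0.34, limma adjusted p = 0.366), fkb 2 (0.27 ± 0.51, adjusted p = 0.73) and fkb 23 (0.06 ± 0.33, adjusted p = 0.911). Among the 100 largest rises of all features at 100 h, 23 were fkb features.

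The tile probes of the fkb region, which cover both strands, rose further on the strand of the genes than on the other. At 100 h in maltose, 395 of 459 sense tile probes rose and 3 fell, with a median change of 4.84, against 165 that rose and 15 that fell among 463 antisense tile probes, with a median change of 0.55. The sense mean rose by 3.99 ± 0.23 (SE) and the antisense mean was 0.68 ± 0.32 higher, a difference of 3.32 ± 0.27 between strands. From 92 to 100 h the antisense tile probes rose too, 308 of 463 with 1 fall (median 1.38, mean 1.51 ± 0.32), against a sense mean of 4.26 ± 0.23. The other 2512 tile probes of the region lay over 15 tile positions from any feature used to call strands, and were not called sense or antisense. Of them 1506 rose and 19 fell from 70 to 100 h, with a median of 2.00.

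**Figure D2:**
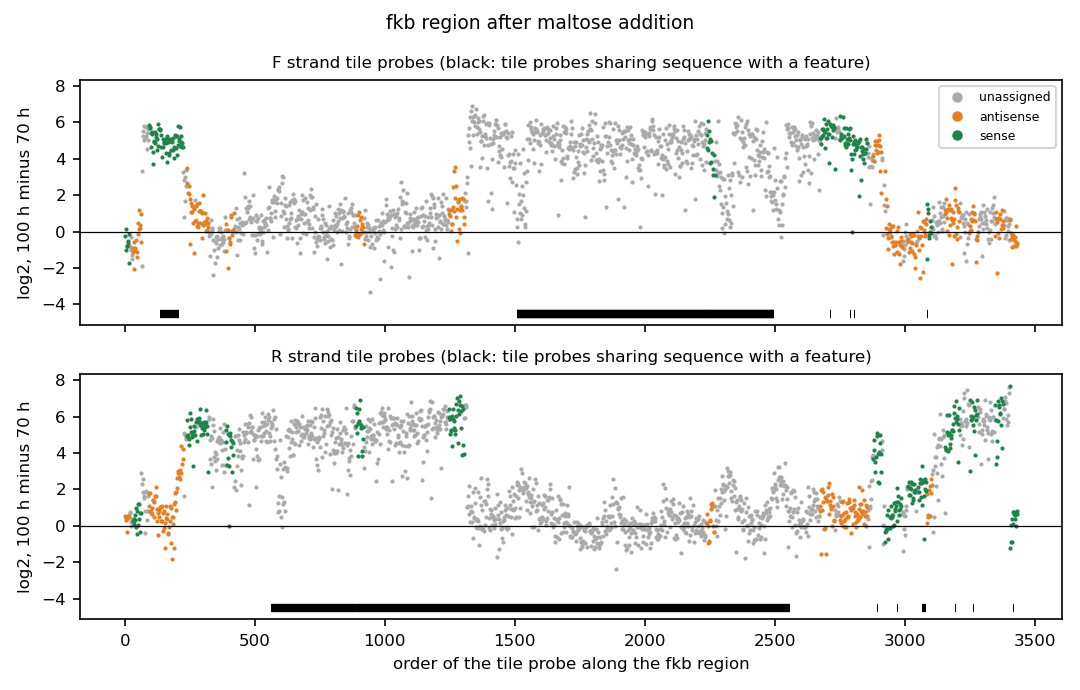
Change of each fkb tile probe in maltose from 70 to 100 h (log2, y axis) by its order along the region (x axis), forward-strand probes above and reverse-strand probes below, coloured by strand relative to the nearest feature, with black marks for probes that share sequence with a feature. Sense probes had a median of 4.84 and antisense probes of 0.55.

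At 70.7 h, the first sample after glucose, pfkA1, pfkA3 and glnR rose and wblA fell. Of the 3 phosphofructokinase genes, which encode the committing enzyme of glycolysis, pfkA3 rose 4.95-fold (2.31 ± 0.40) and pfkA1 3.10-fold (1.63 ± 0.34), with limma adjusted p = 0.000415 and 0.00329, while pfkA2 was at −0.49 ± 0.30 (adjusted p = 0.621). The regulator of nitrogen assimilation glnR rose 2.84-fold (1.51 ± 0.35, limma adjusted p = 0.011). The gene wblA, whose WhiB-like product is required for sporulation and holds back antibiotic synthesis in streptomycetes, fell 4.21-fold (−2.07 ± 0.55, limma adjusted p = 0.0266). All 4 went the same way in both cultures, and the other 15 of the 19 named features outside the fkb region and all 32 fkb features did not pass. Sense tile probes passed for pfkA3, pfkA1 and glnR (1.74, 1.26 and 1.30, limma adjusted p = 6.65e-05, 0.00197 and 0.0159). They did not for wblA (−1.14, adjusted p = 0.0554). As a list, the phosphofructokinase genes averaged 1.15 (camera adjusted p = 0.0147, and adjusted p = 0.123 with an estimated correlation), with 2 of 3 called over all features and over the list alone. The pho region averaged 1.35 (camera adjusted p = 0.0458, and adjusted p = 0.403 with an estimated correlation) and the fkb region −0.23 (camera adjusted p = 0.0432, and adjusted p = 0.7 with an estimated correlation), with 0 features of either called by limma, also over the list alone. After loess the 4 named calls were lost (pfkA3 0.82, pfkA1 0.57, glnR 0.39 and wblA −0.81, limma adjusted p = 0.345, 0.837, 1 and 0.776), and keeping marked backgrounds ended that of wblA (−1.37, adjusted p = 0.148). When culture was a block fkb 12 was gained and the pho list was lost (camera adjusted p = 0.0522).

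Over all features, 386 changed at 70.7 h in glucose, 232 up and 154 down, 379 of them with the same sign in both cultures (limma). With culture as a block the count was 866, without glucose replicate 2 it was 31, and without maltose replicate 1, which entered through the shared spread, it was 758. The self-test at this contrast recovered 78.8% of 4-fold, 17.9% of 2-fold and 2.99% of 1.5-fold changes, with 8.86% false calls. Small simulated changes were thus mostly missed, in arrays drawn without culture or slide effects.

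By the late samples in glucose, 3 of the 4 pho features had risen and the regulators wblA and dasR had fallen. The pho region, a name used for phosphate control, had 4 features, of which pho 1 rose 13.2-fold (3.72 ± 0.96), pho 2 7.53-fold (2.91 ± 0.59) and pho 3 5.59-fold (2.48 ± 0.55), with limma adjusted p = 0.0109, 0.00123 and 0.00322, while pho 4 was at 0.13 ± 0.24 (adjusted p = 0.805). The gene dasR, regulator of N-acetylglucosamine uptake, fell 1.95-fold (−0.97 ± 0.27, adjusted p = 0.0168 by limma) and wblA fell 4.38-fold (−2.13 ± 0.45, adjusted p = 0.00196). Rises were also called for pfkA3 (2.28-fold, 1.19 ± 0.32), glnR (1.92-fold, 0.94 ± 0.29) and SCO6008, a ROK-family regulator (1.69-fold, 0.76 ± 0.23), so that 6 of 19 named features outside fkb rose and 2 fell. Sense tile probes passed for the pho region, wblA, pfkA3 and glnR. They did not for SCO6008 (0.40, limma adjusted p = 0.323) or dasR (−0.70, adjusted p = 0.0583). As a list the pho region averaged 2.31 (camera adjusted p = 0.00525, and adjusted p = 0.209 with an estimated correlation). Of the fkb features 6 fell, and 9 when adjusted over the list alone, with a mean of −0.43 (camera adjusted p = 0.00014, and adjusted p = 0.403 with an estimated correlation). In maltose before 100 h the fkb mean also lay below 70 h. It was −0.30 at 89 h (3 features lower, 0 higher) and −0.25 at 92 h (2 lower, 1 higher). Leaving out 100 h ended the call for SCO6008 (0.72, adjusted p = 0.0621 by limma), and keeping marked backgrounds that for dasR (−0.37, adjusted p = 0.387). Loess left pho 2 and pho 3 past the threshold at 1.00 and 1.05, and ended the other calls (pho 1 1.05, pfkA3 0.20, glnR 0.34, SCO6008 0.52, dasR −0.39 and wblA −0.84). With culture as a block 5 fkb features were gained, and outside the region rshA 1 (−1.12), afsRS (−0.89), pfkA2 (−0.69), absA2 (0.82), pfkA1 (0.63) and SCO1712 (0.34) were gained.

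In all, 904 features changed late in glucose, 383 up and 521 down (limma). The excess of falls turned to 52.4% rises with Cy3 alone and 71.2% with marked backgrounds kept. The count was 1905 with culture as a block, 72 without glucose replicate 2, 1545 without maltose replicate 1 and 472 at 100 h alone.

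After glycerol, glnR was the named gene called at 70.7 h. It rose 2.53-fold (1.34 ± 0.35, limma adjusted p = 0.0314), while pfkA3 was at 0.66 ± 0.40 (adjusted p = 0.725), pfkA1 at 0.32 ± 0.34 and wblA at 0.51 ± 0.55, and the fkb mean was −0.20 with 0 of 32 features called. Sense tile probes of glnR did not pass (1.08, limma adjusted p = 0.0551). After loess the glnR call was lost (0.55, limma adjusted p = 0.869). With culture as a block rshA 2 (0.89, limma adjusted p = 0.0153) and the fkb list (camera adjusted p = 0.032) were gained. With the block the list was tested at the preset correlation only. The strongest unnamed response, that of feature stsu_s_1777, was a 6.23 ± 0.38 rise on the log2 scale (limma adjusted p = 1.75e-12). Over all features 252 changed, 193 up and 59 down, against 503 with culture as a block, 75 without glycerol replicate 1 and 470 without maltose replicate 1.

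Late in glycerol the named genes moved in largely the same directions as late in glucose. Of the pho features 3 rose again, by 10.6-fold at pho 1 (3.40 ± 0.96), 5.75-fold at pho 2 (2.52 ± 0.59) and 5.16-fold at pho 3 (2.37 ± 0.55), with limma adjusted p = 0.0148, 0.00327 and 0.00343, and pho 4 was at 0.36 ± 0.24 (adjusted p = 0.316). Phosphofructokinase genes split, with pfkA3 up 3.12-fold (1.64 ± 0.32), pfkA1 up 1.81-fold (0.86 ± 0.28) and pfkA2 down 1.65-fold (−0.72 ± 0.24), and glnR rose 2.16-fold (1.11 ± 0.29) and SCO6008 1.64-fold (0.72 ± 0.23). Regulators that fell were wblA, 5.79-fold (−2.53 ± 0.45, limma adjusted p = 0.000209), dasR, 2.01-fold (−1.01 ± 0.27, adjusted p = 0.00894), and afsRS, a global activator pair of antibiotic synthesis, 2.10-fold (−1.07 ± 0.33, adjusted p = 0.0237). With rshA 1, which fell 3.08-fold (−1.62 ± 0.44, limma adjusted p = 0.0103), 5 of the 19 named features fell and 7 rose. Sense tile probes passed for the pho region, pfkA3, pfkA1, glnR, wblA and dasR. They did not for SCO6008 (0.13, limma adjusted p = 0.84), pfkA2 (−0.29, 0.268), afsRS (−0.69, 0.0594) or the rshA region (−0.80, 0.139). Those of absA2, a feature not called, passed as well (0.64, limma adjusted p = 0.0145). The pho list averaged 2.16 (camera adjusted p = 0.0195, and adjusted p = 0.302 with an estimated correlation). Among fkb features 5 fell, also over the list alone, with a mean of −0.25 (camera adjusted p = 0.045, and adjusted p = 0.7 with an estimated correlation). In maltose at 92 h the fkb mean was −0.25 as well, with 2 features lower and 1 higher than at 70 h. Leaving out 100 h ended the calls for pfkA1 and afsRS (0.82 and −0.95, adjusted p = 0.0614 and 0.0657 by limma). Loess left pho 3, afsRS and rshA 1 past the threshold at 0.93, −0.80 and −0.74, and a pooled baseline left dasR at −0.60. Under loess the other calls ended (wblA −1.03, pho 1 0.95, glnR 0.65, pho 2 0.57, pfkA3 0.53, dasR −0.30, SCO6008 0.27, pfkA2 −0.20 and pfkA1 0.14). Blocking on culture gained absA2 (0.80), mmyB (0.40) and 6 fkb features.

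The late glycerol count was 1561 features, 578 up and 983 down (limma). It was 3070 with culture as a block, 324 without glycerol replicate 2, 2529 without maltose replicate 1 and 965 at 100 h alone. Of the features called late in glucose and in glycerol, 228 rose in both and 483 fell in both, where independent lists of these sizes would share 23.2 and 53.7, and 2 were called in opposite directions. The baselines of these lists were separate arrays, but both lists also hold changes with time in culture.

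**Figure D3:**
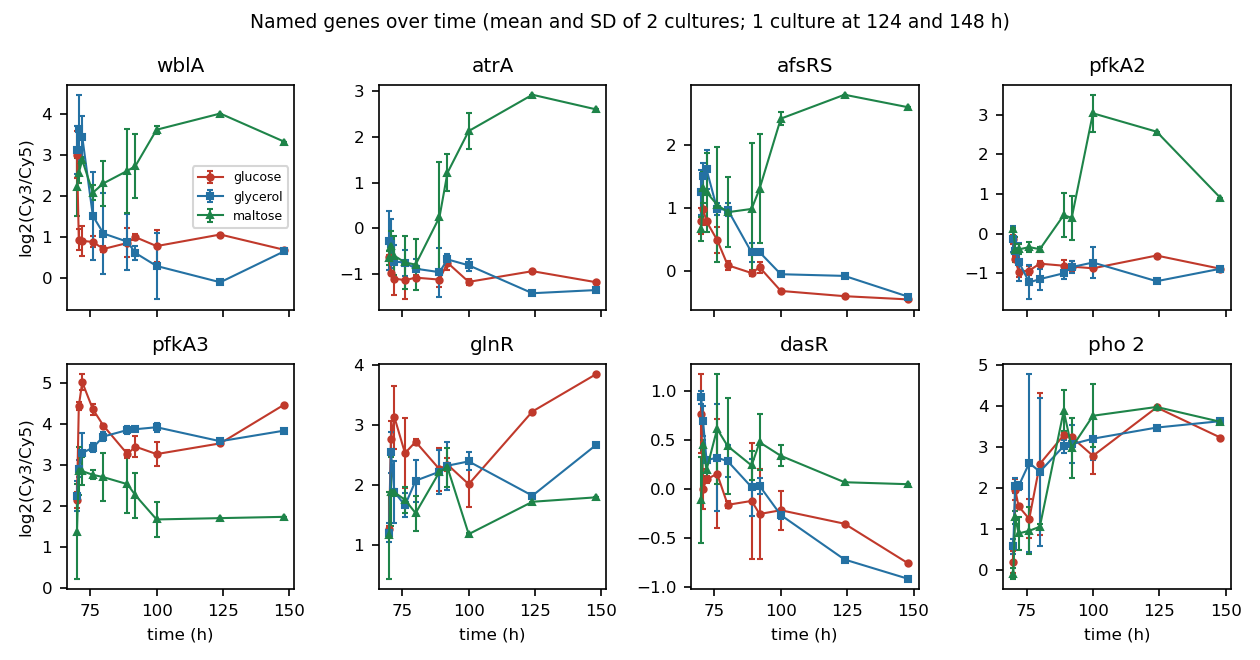
Levels of 8 named features (log2(Cy3/Cy5), y axis) against culture time in hours (x axis), as means with SD of 2 cultures, or 1 culture without a bar at 124 and 148 h. At 100 h atrA, afsRS, pfkA2 and wblA lay higher in maltose than in glucose or glycerol, and pho 2 rose late in all 3 series.

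In the first sample after maltose, pfkA1 and pfkA3 were called, as after glucose. At 70.7 h pfkA3 rose 2.79-fold (1.48 ± 0.40, limma adjusted p = 0.0433) and pfkA1 2.53-fold (1.34 ± 0.34, adjusted p = 0.0325), with pfkA2 at −0.53 ± 0.30 and glnR at 0.73 ± 0.35 (adjusted p = 0.226). Sense tile probes of pfkA3 and pfkA1, on the same arrays, passed at 0.86 and 0.95 (limma adjusted p = 0.0488 and 0.0185). Feature stsu_s_0144 rose by 5.79 ± 0.44 in maltose and by 5.39 ± 0.44 in glucose (limma adjusted p = 7.25e-10 and 3.99e-09), and its response in glycerol was lower than in maltose by −6.18 ± 0.62. The 70 h array of maltose replicate 1 stood apart, with a median Cy3 signal of 1465 against 218 to 359 on the other 5 arrays at 70 h. Without it both phosphofructokinase calls were lost (pfkA3 0.66 and pfkA1 0.94, both at adjusted p = 0.93 by limma), as they were after loess (0.32 and 0.11) and with a pooled baseline (0.93 and 1.02). The culture block gained rshA 2 (0.71, limma adjusted p = 0.0339), fkb 28 and fkb 32. Over all features 228 changed, 185 up and 43 down, against 1686 with culture as a block, 12 without that array, 13 without maltose replicate 1 and 2209 without maltose replicate 2.

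Late in maltose, atrA, pfkA2, 3 of the 4 pho features and 25 of the 32 fkb features rose. The gene atrA, which encodes a TetR-family activator of actinorhodin synthesis in a related species, rose 3.60-fold (1.85 ± 0.34, limma adjusted p = 0.000307), and its change was 6.86-fold at 100 h (2.78 ± 0.42). Phosphofructokinase gene pfkA2 rose 2.27-fold (1.18 ± 0.24, limma adjusted p = 0.000851), a rise that lay at 100 h (2.92 ± 0.30) and not over 89 and 92 h alone (0.31, adjusted p = 0.406), and that loess ended (0.01, adjusted p = 0.98). The pho features rose 21.8-fold at pho 1 (4.44 ± 0.96), 12.4-fold at pho 2 (3.63 ± 0.59) and 6.90-fold at pho 3 (2.79 ± 0.55), with limma adjusted p = 0.0014, 7.21e-05 and 0.000651, and pho 4 was at −0.23 ± 0.24 (adjusted p = 0.489). The fkb features averaged 1.30, with 25 of 32 up (26 up and 1 down over the list alone, camera adjusted p = 1.5e-13, and adjusted p = 0.123 with an estimated correlation), through the 100 h samples described above. Calls for afsRS (1.88-fold, 0.91 ± 0.33), pfkA1 (1.66-fold, 0.73 ± 0.28, but −0.27 after loess and −0.30 with Cy3 alone) and mmyB (1.34-fold, 0.43 ± 0.16) completed the 8 of 19 named features that rose, and 0 fell. Sense tile probes passed for atrA (0.65), pfkA2 (0.89) and the pho region (2.04). For afsRS, pfkA1 and mmyB they gave 0.59, 0.35 and 0.02 and did not pass (limma adjusted p = 0.112, 0.347 and 0.981). Without the bright 70 h array these 3 calls and that of pho 1 were lost, at 0.77, 0.33, 0.44 and 4.35 (limma adjusted p = 0.36, 0.644, 0.264 and 0.0507). Loess also ended the calls of pho 1 (1.02) and afsRS (0.49), and left atrA at 0.71, pho 2 at 1.01, pho 3 at 0.83 and mmyB at 0.95. A pooled baseline ended that of pfkA1 (0.41, limma adjusted p = 0.13). Without 100 h the calls of afsRS (0.48, limma adjusted p = 0.333) and mmyB (0.38, adjusted p = 0.111) were lost as well. As lists, the pho region averaged 2.66 (camera adjusted p = 0.0425, and adjusted p = 0.394 with an estimated correlation) and the phosphofructokinase genes 0.90 (camera adjusted p = 0.0636, 3 of 3 up over the list alone). When culture was a block the phosphofructokinase list passed (camera adjusted p = 0.0443, at the preset correlation, the only one tried with the block). The features pfkA3 (0.78), wblA (0.77), glnR (0.74), fkb 23, fkb 28 and fkb 32 were gained.

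In all 2693 features changed late in maltose, 1508 up and 1185 down (limma). The count was 4225 with culture as a block, 476 without the bright 70 h array, 454 without maltose replicate 1 and 4470 without maltose replicate 2. By single times against 70 h it was 49 at 72 h, 40 at 80 h, 948 at 89 h, 1844 at 92 h and 2865 at 100 h, while in glucose it peaked at 871 at 72 h and in glycerol at 965 at 100 h. For the late mean, fits on only the series compared gave 461 in maltose and 1495 in glucose, so the larger late count of maltose held only with the pooled spread. The maltose spread includes the bright 70 h array. Counts at single times were not refitted in this way. From 92 to 100 h, 1146 features changed in maltose, 746 up and 400 down, and limma called 0 in glucose (51 at an unadjusted p under 0.05) and 0 in glycerol (81).

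**Figure D4:**
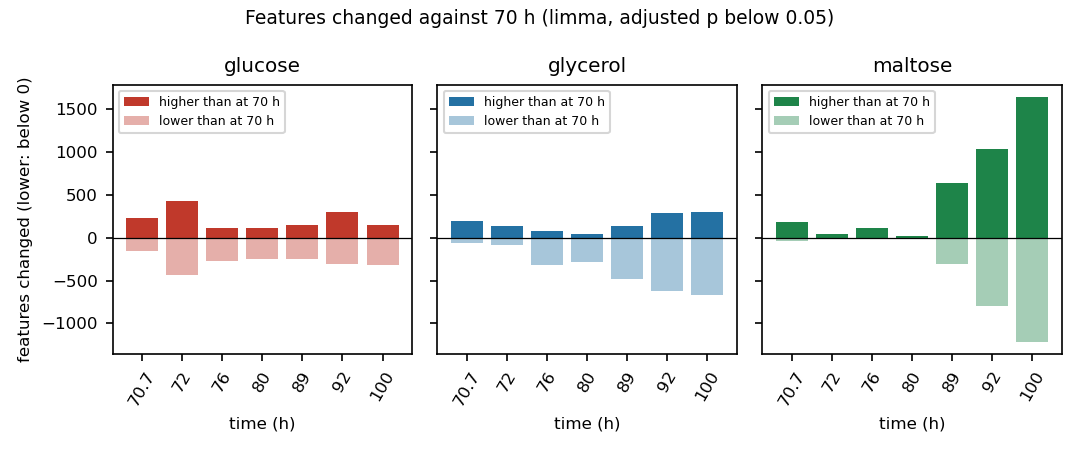
Number of features changed against 70 h of the same series (y axis, rises above 0 and falls below) at each later time in hours (x axis), for glucose, glycerol and maltose (limma, adjusted p below 0.05). The bars reach 2865 features in maltose at 100 h, 871 in glucose at 72 h and 965 in glycerol at 100 h. All counts use a spread pooled over all series.

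The responses to glucose and to glycerol were set against the response to maltose, each measured from its own 70 h samples. Late calls split by the opening letters of the identifier. Among stsu_s features, which include the named ones outside fkb, 453 were higher and 901 lower with glucose, and 744 and 1335 with glycerol. With glucose stsu_u features also went mostly lower (66 and 129), but stsur_sf (88 and 27) and stsur_sr (83 and 19) mostly higher. Whether array brightness made this split was not tested. Late, 5 named genes outside fkb responded lower with glucose than with maltose: wblA by −2.90 ± 0.64 (7.46-fold), atrA by −2.24 ± 0.48 (4.72-fold), pfkA2 by −1.87 ± 0.34 (3.66-fold), afsRS by −1.80 ± 0.46 (3.48-fold) and dasR by −1.43 ± 0.37 (2.70-fold), with limma adjusted p = 0.0024, 0.00199, 0.000444, 0.00709 and 0.0081. By scan set these were −1.77 and −4.03 for wblA, −2.05 and −2.43 for atrA, −1.92 and −1.82 for pfkA2, −1.03 and −2.57 for afsRS, and −1.06 and −1.81 for dasR. Sense tile probes gave −1.88 for wblA, −1.23 for pfkA2 and −1.11 for afsRS (limma adjusted p = 0.00453, 0.000397 and 0.0307). They did not pass for atrA (−0.56, limma adjusted p = 0.179) or dasR (−0.66, adjusted p = 0.235). In the other direction, sense tile probes of absA2, a feature not called, passed higher with glucose (0.75, limma adjusted p = 0.0488). Without the bright 70 h array the calls of afsRS and dasR were lost (−1.66 and −1.12, limma adjusted p = 0.0634 and 0.109), and without the 100 h samples those of afsRS and pfkA2 (−1.27 and −0.98, adjusted p = 0.0827 and 0.0687). A pooled baseline left dasR at −0.55 (limma adjusted p = 0.0406), keeping marked backgrounds ended its call (−0.84, adjusted p = 0.157), and Cy3 alone left wblA at −1.77. Loess left afsRS at −1.27 and ended the calls of atrA (−0.95, limma adjusted p = 0.0718), wblA (−0.41, 0.634), pfkA2 (−0.35, 0.488) and dasR (−0.33, 0.411). Blocking on culture gained rshA 1 (−1.28) and 3 fkb features. Over all features 2118 differed, 949 higher and 1169 lower with glucose, against 3493 with culture as a block, 684 without the bright array, 211 without glucose replicate 2, 4052 without maltose replicate 2 and 1183 without 100 h. At 70.7 h 29 features differed (16 higher, 13 lower), 155 with culture as a block, 11 without the bright array, 1 without glucose replicate 2 and 1412 without maltose replicate 2, and of the 51 named features none passed without the block and wblA with it (−2.42, limma adjusted p = 0.0157).

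Glycerol set against maltose gave the same 5 named genes and rshA 1 lower. The late differences were −3.30 ± 0.64 for wblA (9.85-fold), −2.39 ± 0.48 for atrA (5.26-fold), −1.98 ± 0.46 for afsRS (3.93-fold), −1.90 ± 0.34 for pfkA2 (3.73-fold), −1.78 ± 0.62 for rshA 1 (3.44-fold) and −1.47 ± 0.37 for dasR (2.77-fold), with limma adjusted p = 0.000411, 0.000579, 0.00214, 0.000202, 0.0271 and 0.00402. Scan sets gave −2.37 and −4.23 for wblA, −2.49 and −2.30 for atrA, −1.58 and −2.37 for afsRS, −1.89 and −1.90 for pfkA2, −1.12 and −2.45 for rshA 1, and −1.13 and −1.81 for dasR. Sense tile probes gave −2.34 for wblA, −1.28 for afsRS and −1.18 for pfkA2 (limma adjusted p = 0.000456, 0.0117 and 0.000557). They did not pass for atrA (−0.56, limma adjusted p = 0.184), the rshA region (−1.09, adjusted p = 0.16) or dasR (−0.83, adjusted p = 0.112). Without the bright array dasR and rshA 1 were lost (−1.16 and −1.94, limma adjusted p = 0.0647 and 0.0712), and without 100 h rshA 1 was lost (−1.52, adjusted p = 0.0841). A pooled baseline ended the call of dasR (−0.42, limma adjusted p = 0.1) and left rshA 1 at −1.06. Loess left atrA at −1.10 and afsRS at −1.29 and ended the calls of rshA 1 (−0.61, limma adjusted p = 0.15), wblA (−0.60, 0.434), dasR (−0.25, 0.536) and pfkA2 (−0.21, 0.693). The culture block gained pfkA3 (0.86), argR (−0.78), fkb 1 and fkb 23, and at 70.7 h fkb 16. Late, 3256 features differed, 1530 higher and 1726 lower with glycerol, against 1434 without the bright array and 1201 without maltose replicate 1. At 70.7 h 145 differed, 96 higher and 49 lower, against 325 with culture as a block, 46 without glycerol replicate 1 and 1309 without maltose replicate 2, and stsu_s_1777 stood 6.09 ± 0.53 higher with glycerol (limma adjusted p = 1.5e-08).

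Glucose and glycerol were set against each other at 70.7 h and late, and not at 72, 76 or 80 h. At 70.7 h 249 features responded differently, 126 higher and 123 lower with glucose (limma), against 442 with culture as a block, 568 with a pooled baseline and 70 without glucose replicate 2. Feature stsu_s_1777 was lower with glucose by −6.01 ± 0.53 and stsu_s_0144 higher by 5.79 ± 0.62 (limma adjusted p = 1.5e-08 and 4.65e-07). Of the 51 named features none passed without the block, and 3 passed with culture as a block: wblA at −2.59 (limma adjusted p = 0.0854 without and 0.00212 with the block), pfkA3 at 1.65 (0.173 and 0.00161) and pfkA1 at 1.31 (0.245 and 0.0154). As a list the phosphofructokinase genes were 0.92 higher with glucose (camera adjusted p = 0.045, and adjusted p = 0.202 with an estimated correlation), with 2 of 3 called when adjusted over the list alone. Late, 8 features differed, 4 in each direction, against 35 with culture as a block, 329 with a pooled baseline, 0 without glycerol replicate 2 and 40 without maltose replicate 1, and 366 met an unadjusted p under 0.05. The fkb difference between these sources was −0.18 late (limma's camera, adjusted p = 0.0807) and −0.03 at 70.7 h.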

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

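The strand test, the tests on features of equal level and the fits without the bright maltose array at 70 h were chosen only after the results were seen.

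Among the 6 arrays at 70 h, 22 measures were checked for a lone extreme array, and 3 had a gap to the nearest array, as a share of the range, above Dixon's 95% limit, where chance marks about 1 measure in 20. The median Cy3 signal reached 0.887, with 1465 on the array of maltose replicate 1 and 218 to 359 on the others. The gene atrA reached 0.775, with a level of 0.20 in glycerol replicate 1 and −0.76 to −0.54 elsewhere. The gene pfkA3 reached 0.73, with a level of 0.55 in maltose replicate 1 and 1.97 to 2.50 elsewhere.

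The remaining results of this part are differences between the responses of 2 series, each tested as an interaction by limma. The fkb region responded lower late with glucose than with maltose (−1.72) and lower with glycerol than with maltose (−1.55). With an estimated correlation between genes both list calls were lost (camera adjusted p = 0.123 and 0.202). The weaker scan set gave −1.69 for glucose and −1.41 for glycerol, which decided nothing about scan sets, since each culture stayed in 1 set up to 100 h and a difference between sets cancels in its own change. Without the bright maltose array at 70 h the differences were −1.77 and −1.60, and past the threshold with the preset correlation, which argued against that array as the whole cause. Brightness or centring as the whole cause was argued against at 100 h, where the fkb means differed by −4.86 and −4.68 and 314 and 312 other features with the same level at 70 h had median differences of 0.132 (SD 1.47) and 0.128 (SD 1.5), while over 89 and 92 h alone the fkb differences were −0.15 and 0.02. For the rise from 92 to 100 h in maltose (4.69) the same was argued by 317 other features of equal level at 92 h, with a median change of 0.0829 (SD 0.782). A strand test of the late differences decided nothing, because sense minus antisense also went below 0 in 8 of 8 and 6 of 6 regions with no sense change at an unadjusted p under 0.05.

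Features that responded differently numbered 29 at 70.7 h and 2118 late for glucose against maltose, 145 and 3256 for glycerol against maltose, and 249 and 8 for glucose against glycerol. For each late comparison the 4 cultures allow 3 assignments to 2 pairs, too few to give a share under 0.05. In each, 1 of 3 assignments, the real one, gave as many features (2118, 3256 and 8), and the highest other gave 0, 1 and 0. The other assignments mix the sources within both pairs, so a difference between sources of any cause widens their spread. Their low counts therefore decided nothing.

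With a spread pooled over all series, the broad late change of the maltose series, 2693 features, was larger than the 904 of the glucose series. Against 1495 for glucose, it was 461 in fits on only the series compared. Without the bright maltose array at 70 h it was 476, below the glucose count, so the size of the list depended on that array, but leaving it out also leaves 1 array at that baseline and lowers the power. Differences stayed about as large without it for atrA (1.95 from 1.85), pho 3 (2.98 from 2.79) and pho 1 (4.35 from 4.44), although the call of pho 1 was lost (limma adjusted p = 0.0507), and pfkA1 was at 0.33 from 0.73. From 92 to 100 h, with no 70 h array involved, 1146 features changed in maltose and 0 in glucose or glycerol. The late changes of the 2 cultures correlated at r = 0.454 over features that are not independent replicates, which decided nothing about scan sets for the reason given above. How much of the count is a response to maltose stayed open.

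Late differences of single named genes, glucose then glycerol against maltose, were −2.90 and −3.30 for wblA. They were −2.24 and −2.39 for atrA. For pfkA2 they were −1.87 and −1.90. The afsRS values were −1.80 and −1.98. The dasR values were −1.43 and −1.47. For rshA 1 the glycerol difference alone was called, at −1.78.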

How the results depend on the processing

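The settings listed last, from centring on all spots onward, were chosen only after results were seen. The fkb differences kept their direction and side of the threshold under 25 of 27 alternatives, both for glucose and for glycerol against maltose. These 25 all took the preset correlation between genes of 0.01, while the estimate for the fkb features was 0.297. They therefore say nothing about that choice, and with the estimate both calls were lost. Counts moved widely with the arrays included, and dim spots limit what low-expressed features can show. Without 1 culture at a time the lone remaining culture was assumed to vary like the other groups. Unless a reason is given, the cause was not tested. Counts follow the order glucose, glycerol and maltose at 70.7 h and late, then glucose against maltose, glycerol against maltose and glucose against glycerol.

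Leaving out 1 culture at a time gave 31 to 758 features for glucose at 70.7 h and 72 to 1545 late, 75 to 470 and 324 to 2529 for glycerol, 13 to 2209 and 454 to 4470 for maltose, 1 to 1412 and 211 to 4052 for glucose against maltose, 46 to 1309 and 1201 to 4690 for glycerol against maltose, 70 to 379 and 0 to 40 for glucose against glycerol, and 0 to 2403 for the 70 h series. The fkb differences ranged from −1.84 to −1.61 and from −1.76 to −1.33.

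With culture as a replicate block, which takes the lasting differences of the paired cultures out of the spread, 866 and 1905 features changed in glucose, 503 and 3070 in glycerol and 1686 and 4225 in maltose, and 155 and 3493 differed for glucose against maltose, 325 at 70.7 h for glycerol against maltose, and 442 and 35 for glucose against glycerol. Among named features it lost none of the 46 calls outside the fkb region and 85 within it, and gained 20 and 23. Of the lists it gained the fkb region in glycerol at 70.7 h and the phosphofructokinase genes in maltose late, and lost the pho region in glucose at 70.7 h (camera adjusted p = 0.032, 0.0443 and 0.0522). An estimated correlation was not tried with the block.

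Loess within arrays gave 103 and 485 for glucose, 60 and 810 for glycerol, 24 for maltose at 70.7 h, 3 and 944 for glucose against maltose, 25 and 1649 for glycerol against maltose, 34 and 0 for glucose against glycerol (limma), and 0 at 70 h. It turned pfkA1 late in maltose to −0.27, and Cy3 alone turned it to −0.30. Loess may also have removed real changes, because of the common reference. Agilent processed signals gave 1377 for glucose late and 15 for glucose against maltose at 70.7 h. Quantile scaling gave 433 for maltose at 70.7 h, 13 for glucose against glycerol late and 2 at 70 h. Cy3 alone gave 18 for glucose against maltose at 70.7 h and 3 at 70 h. The authors' table gave 52 for maltose at 70.7 h, 44 for glucose against maltose at 70.7 h and 16 for glucose against glycerol late.

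Slide as a random block (correlation 0.379) gave 705 and 1524 for glucose, 395 for glycerol at 70.7 h, 358 for maltose at 70.7 h, 97 and 3374 for glucose against maltose, 431 for glucose against glycerol at 70.7 h and 5 at 70 h. Slide as a fixed term gave 613 and 1457 for glucose, 23 for maltose at 70.7 h, 458 for glucose against glycerol at 70.7 h and 5 at 70 h. A pooled baseline gave 674 and 2054 for glucose, 560 and 2715 for glycerol, 62 for maltose at 70.7 h, 57 and 4216 for glucose against maltose, 253 and 4986 for glycerol against maltose, and 568 and 329 for glucose against glycerol. Fits on only the series compared, which pool the spread over fewer arrays, gave 774 and 1495 for glucose, 16 and 461 for maltose, 9 for glucose against maltose and 83 for glycerol against maltose at 70.7 h, and 379 and 40 for glucose against glycerol. With an estimated correlation between genes the fkb differences of −1.72 and −1.55 missed the threshold (adjusted p = 0.123 and 0.202 by limma's camera).

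Centring on all spots gave 13 for glucose against maltose at 70.7 h and 5 for glucose against glycerol late, and plain subtraction for Cy5 gave 5 for the latter. Keeping the marked backgrounds gave 54 for maltose at 70.7 h, 13 and 1198 for glucose against maltose, 32 for glucose against glycerol late and 4 at 70 h. Without the bright maltose array at 70 h, 12 and 476 features changed in maltose, 11 and 684 differed for glucose against maltose, 1434 for glycerol against maltose late and 2 at 70 h. Late as 89 and 92 h gave 1183 for glucose against maltose, 13 for glucose against glycerol, and fkb differences of −0.15 and 0.0185. Late as 100 h alone gave 472 for glucose, 965 for glycerol and 2 for glucose against glycerol.

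The share of rises among calls moved by over 10 points as follows. For glucose it was 60.1% at 70.7 h (Cy3 alone 48.6%, marked backgrounds kept 84.7%) and 42.4% late (52.4% and 71.2%). For glycerol it was 76.6% at 70.7 h (loess 90.0%) and 37.0% late (loess 26.3%, processed signals 47.5%, deposited values 49.2%). For maltose it was 81.1% at 70.7 h (loess 91.7%, quantile 53.8%, marked backgrounds kept 96.3%) and 56.0% late (loess 42.4%, Cy3 alone 44.5%). For glucose against maltose it was 55.2% at 70.7 h (loess 66.7%, deposited values 65.9%, all spots 76.9%, marked backgrounds kept 100%) and 44.8% late (loess 57.8%, Cy3 alone 55.6%). For glucose against glycerol it was 50.6% at 70.7 h (marked backgrounds kept 65.9%) and 50% late (quantile 61.5%, Cy3 alone 63.6%, deposited values 68.8%, marked backgrounds kept 84.4%).

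The median of all features moved by over 0.1 as follows. Loess took late glycerol from 0.16 to 0.04, late maltose from 0.05 to −0.11 and late glucose against maltose from 0.03 to 0.20. For the last, processed signals gave 0.13, Cy3 alone 0.15 and the deposited values 0.16. Cy3 alone gave 0.03 for late glycerol. The authors' table gave −0.07 for late maltose, and for glycerol against maltose −0.01 at 70.7 h (from −0.11) and 0.20 late (from 0.06). Centring on all spots gave 0.30 for maltose at 70.7 h (from 0.13), −0.27 for glucose against maltose at 70.7 h (from −0.10), and −0.26 and −0.05 for glycerol against maltose. Keeping marked backgrounds took late glucose from 0.09 to −0.05.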

Other observations

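The tests of this part, those by strand and the one on the speed of the cultures, were all chosen only after the results were seen.

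The wblA region changed in opposite directions on its 2 strands late in glucose. Its sense tile probes fell by 1.30 ± 0.32 (SE, limma adjusted p = 0.00579) while its antisense tile probes rose by 2.87 ± 0.25 (adjusted p = 8.7e-10). Late in glycerol the sense tile probes fell by 1.75 ± 0.32 (limma adjusted p = 0.000272), and the antisense response was 2.64 ± 0.35 higher with glucose than with glycerol (adjusted p = 3.94e-06). Late in maltose the antisense tile probes rose as well, by 1.08 ± 0.25 (limma adjusted p = 0.00296), with sense tile probes at 0.59 ± 0.32 (adjusted p = 0.254), and the antisense response was 1.79 ± 0.35 higher with glucose than with maltose (adjusted p = 0.000481). Sense minus antisense there also went below 0 (−1.26 to −0.43) in 8 of 8 regions with no sense change at an unadjusted p under 0.05. A shift towards antisense against maltose was therefore not particular to wblA. At 70 h sense tile probes were brighter than antisense tile probes in 15 of the 16 regions, SCO1712 being the other at −0.38. The feature wblA was at 3.01 at 70 h and 0.93 at 70.7 h in glucose, and in glycerol at 3.64 at 70.7 h, 3.45 at 72 h and 1.51 at 76 h (n = 2 cultures).

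The samples of 124 and 148 h, 1 culture per source, entered no comparison. At these times atrA was at 2.92 and 2.60 in maltose, −0.93 and −1.18 in glucose, and −1.42 and −1.35 in glycerol. The level of afsRS was 2.80 and 2.60 in maltose, −0.41 and −0.46 in glucose, and −0.08 and −0.41 in glycerol. The level of pfkA2 was 2.57 and 0.90 in maltose, −0.56 and −0.89 in glucose, and −1.20 and −0.89 in glycerol. The level of wblA was 4.02 and 3.33 in maltose, 1.06 and 0.69 in glucose, and −0.11 and 0.65 in glycerol.

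Maltose replicate 2 trailed replicate 1 in the late maltose change, scored as the mean signed change from the 70.7 to 80 h samples over the 2693 features called. The scores at 89, 92 and 100 h were 0.807, 0.804 and 1.05 in replicate 1 and 0.287, 0.638 and 1.05 in replicate 2. A test of different speeds, whether replicate 2 reached the 100 h score of replicate 1 later on, decided nothing: at 124 h it was at 1.26, but the gap had already closed by 100 h, the scored features were chosen for this change, and the 124 h array lay in another scan set than the earlier arrays of that culture. The cause of the gap stayed open.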
